A study of Homo sapiens with 15 samples.

How the data were processed

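Poly(A)+ RNA was sequenced from 15 HEK293T libraries, 12 of them from cells transfected for 48 h with 100 ng of a plasmid for a dead Cas protein fused to the ADAR2 deaminase domain and 400 ng of a guide RNA plasmid, and 3 from cells taken as untransfected by their titles and characteristics. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit, per the labels. The labels name cutadapt 1.14, STAR 2.5.2b, SAMtools 1.5, featureCounts 1.5.0 and Subread, without role or order, and the build hg19. The gene annotation and the program that listed edited positions are not given in the sources used here.

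The authors deposited gene expression as TPM, reads per gene length scaled to one total within each library, in a paired-end table for the transfected libraries and a single-end table for the untransfected ones, with 57820 genes in the paired-end table. For each library the authors also deposited a list of positions with read coverage, base change and edited fraction. The deposited score of each position is a confidence from 0 to 1. It was checked to equal the probability that a Beta variable with the edited and unedited reads as its parameters is over 0.01, with a largest difference of 5e-10, and to be 0 where no unedited read is listed. Coverage multiplied by fraction lay within 5e-07 of a whole number at every position, so edited reads were taken from it. Over all libraries 1275414 entries at 884202 positions were listed, 1347 of them in all 12 transfected libraries, and 25 had more than 1 alternative base. A position missing from a list has no stated depth. Neither a genome sequence nor an annotation of hg19 was used here, so positions carry no gene, exon or sequence context.

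Read totals were recovered from the TPM values, because a gene's TPM is a whole number of reads times a constant for its length and library. Gene lengths recovered this way were whole numbers within 0.0001 nt for 99.99% of 13687 genes with at least 500 reads. Recovered totals ranged from 11903762 to 59593185 reads in transfected and from 11944707 to 19161712 reads in untransfected libraries. They set the precision of an expression value, while the coverage of a position sets that of an edited share, given with its exact Clopper-Pearson 95% interval.

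Groups followed the labels: 3 fusions with 2 guides and 2 libraries each. In the deposited expression data the names of the 2 dCas9 CYFIP2 libraries carry an extra tag, NS, which their titles lack. They were matched as the only ones with that fusion, guide and number, and the meaning of the tag was not resolved here. Tests, contrasts, filters, 25 gene lists and the rule for naming genes and positions were set before the data were examined. Of the 630 list entries 622 matched a gene in the table and 518 were tested. By that rule the text names all genes that passed or, with none, those with the smallest p-values, up to 4 passing members per list, CYFIP2, ADAR, ADARB1, ADARB2 and NCKAP1, the 10 positions with the highest level, and the 5 positions with the smallest p in each direction. The text gives only some of these in full. WARS1, SHMT2, CEBPB and TRIB3 are the integrated stress response members with the smallest p for dCas13d against dCas9, and the further members listed with them were chosen after their values were seen. CYFIP1 could not be matched by its identifier and was not analysed here.

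Expression was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1) for 15679 genes with a mean of at least 1 TPM over the transfected libraries, with a mean per group, a spread shared by the 6 groups and a mean-variance trend. P-values are two-sided and adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. Guide contrasts were taken within each fusion and as the mean over fusions, fusion contrasts over both guides, and a moderated F tested whether the guide effect differed between fusions. Gene lists with at least 5 tested members, 22 of the 25, were tested by camera with a preset correlation of 0.01 and adjusted over 154 tests. Blood, carcinoma epithelial and neural marker lists had fewer tested members. No expression test was made between the transfected and untransfected tables.

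Numbers of A-to-G positions with a coverage of at least 10 were compared on the log10 scale by two-sided exact permutation tests, within fusions for the guide. With 70 arrangements of 4 against 4 the smallest p is 0.0286, and with 216 arrangements of guides within fusions it is 0.00926. Editing levels at 1141 positions listed with that coverage in all transfected libraries were fitted by a quasi-binomial model of edited and unedited reads, with the dispersion moderated by limma and F tests adjusted over positions. Positions where a group had no edited or no unedited read were left out. Correlations used values centred within fusions and 100000 permutations. Families of permutation tests were adjusted by Benjamini-Hochberg.

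On simulated data with the spread of these libraries, limma recovered 30% of genes with a log2 change of 1 and 78% with a change of 2 for the dCas9 guide contrast, and 75% and 94% over the 3 fusions, with 5 and 4 false calls among 15679 genes. Without the spread of dCas9 NT a change of 1 was recovered at 55% and 90%. These simulations drew each gene independently, with the same spread in every library. Patterns shared across genes and the wider spread within dCas9 NT are absent from them, so real recovery and false calls can differ. The quasi-binomial fit recovered 41% of positions with a log odds change of 1, with 0 false calls. That simulation drew positions independently, with the same preset spread for every position and library and not one estimated from these data. Its recovery and false calls can therefore differ from the real ones too. Alternatives covered pseudocounts, filters, scaling, a replicate block, voom, library weights, coverage, confidence and fraction minimums, thinning to one coverage, lists drawn to equal length, and leaving out each library. Replicate numbers do not pair the libraries: of 15 correlations between groups of their replicate differences, from -0.212 to 0.393, 1 was over 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.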

Results

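Poly(A)+ RNA was sequenced from HEK293T cells, an immortalized human kidney line, 48 h after transfection with a plasmid for an RNA editor and a plasmid for its guide RNA. Each editor joined the deaminase domain of ADAR2, the enzyme encoded by ADARB1 that turns adenosine in RNA into inosine (read as G), to a catalytically dead Cas protein: dCas9, dCas13b or dCas13d. Each of the 3 fusions was combined with a guide against the CYFIP2 transcript or with a non-targeting (NT) guide, with 2 libraries for each of the 6 combinations, and 3 libraries came from cells taken here as untransfected. Their titles and characteristics say untransfected and untreated, while their treatment field repeats the transfection protocol, and every comparison with them rests on the former. For every library the data hold gene expression in TPM, reads per gene length scaled to one total per library, and a list of A-to-G positions with their read coverage and edited fraction. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures a difference only against the spread between these libraries. The untransfected libraries stand in a single-end expression table and the transfected ones in a paired-end table, so sequencing layout and transfection cannot be told apart.

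The read totals recovered from the TPM values gave the depth of each library. With the CYFIP2 guide they were 44014064 and 59593185 reads for dCas9, 40179859 and 17348074 for dCas13b, and 30502629 and 41300428 for dCas13d. With the NT guide they were 11903762 and 13244498 reads for dCas9, 43390242 and 19267514 for dCas13b, and 14637635 and 44354496 for dCas13d. The untransfected libraries held 11944707, 14202648 and 19161712 reads. The dCas9 NT libraries, which were the shallowest of the transfected ones, also lay far apart in expression: on the first principal component, which held 50.4% of the variance, replicate 2 stood at 0.733 and replicate 1 at -0.112. Both dCas13b NT libraries lay on the side of dCas9 NT replicate 2, at 0.355 and 0.241, and the other libraries lay between -0.355 and -0.056.

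Editing at the targeted transcript answers whether each fusion acts where its guide directs it. The CYFIP2 guide libraries of all 3 fusions listed an edited A at position 156736808 on the plus strand of chromosome 5 (hg19), while none of the 6 NT guide libraries listed it. CYFIP2 encodes a subunit of the WAVE complex that controls actin assembly, and this position is its known lysine-to-glutamic-acid recoding site in this build as background knowledge, not from an annotation, since no hg19 annotation was used here. Across the CYFIP2 guide libraries the edited share was 10.5% ± 5.23 (SD, n = 6). It was 12.8% ± 4.88 (SD, n = 2) for dCas13d, 10.2% ± 8.17 (SD, n = 2) for dCas9 and 8.38% ± 5.12 (SD, n = 2) for dCas13b.

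Per library, dCas13d gave 6 of 64 reads (9.38%, exact Clopper-Pearson 95% interval 3.52% to 19.3%) and 7 of 43 reads (16.3%, 6.81% to 30.7%). For dCas9 the counts were 8 of 50 reads (16.0%, 7.17% to 29.1%) and 2 of 45 reads (4.44%, 0.543% to 15.1%). For dCas13b they were 2 of 42 reads (4.76%, 0.582% to 16.2%) and 3 of 25 reads (12%, 2.55% to 31.2%). The intervals overlap and cover counting error only, and a difference between fusions at this position was not tested. As background, 1 of the 3 untransfected libraries listed the site, with 1 edited read of 16 (6.25%, 0.158% to 30.2%). With an unlisted site counted as 0, the guide difference of 10.5 percentage points had p = 0.00926 in a two-sided exact permutation test of guide labels within fusion, the smallest p that its 216 arrangements can give. An unlisted site has no stated depth. The position was picked as the only one in the searched window listed in all 6 CYFIP2 guide libraries and in no NT guide library. It was also the one with the largest guide difference there. With unlisted sites counted as 0, picking it this way fixed the p at its smallest value in advance. The p is therefore no evidence of editing by the guide.

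**Figure D1:**
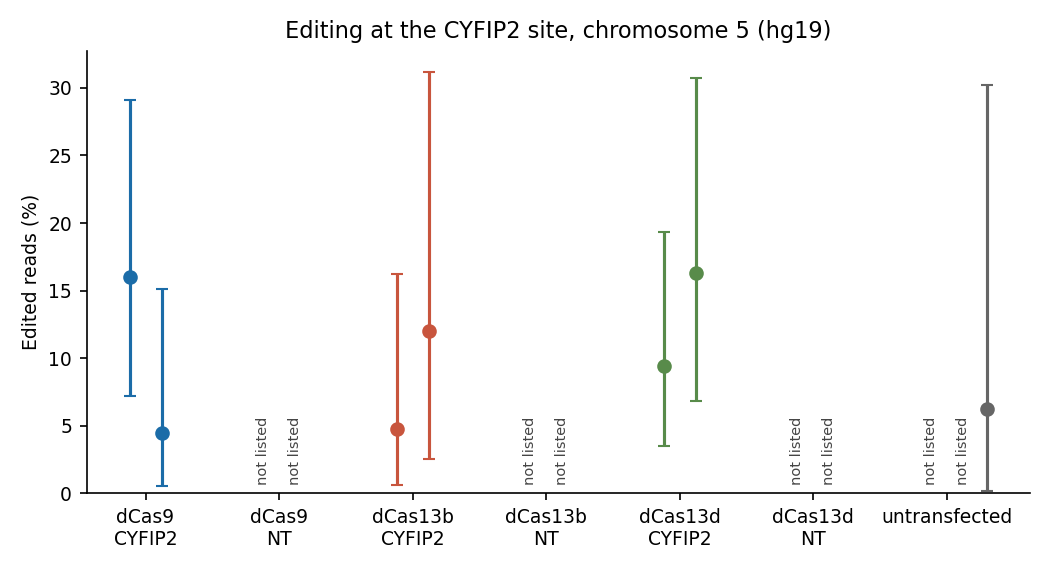
Share of edited reads (%) at position 156736808 of chromosome 5 in each library, grouped by fusion and guide; points are libraries and bars are exact Clopper-Pearson 95% intervals. The 6 CYFIP2 guide libraries lie between 4.44% and 16.3%, the NT guide libraries do not list the site, and 1 untransfected library lists it at 6.25%.

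The same listing pattern, present in all 6 CYFIP2 guide libraries and in no NT guide library, held at 16 positions in the whole lists, against 1 position with the reverse pattern. Of the 216 ways to assign guide labels evenly within fusions, 18 gave at least as many positions, and the highest other assignment gave 38. The targeted position ranked 9th of the 16 by mean level, the highest of which was 68.9%. Within 100 nt of the targeted position, 8 of the 12 transfected libraries listed no other A-to-G site, and the other libraries listed from 1 to 3.

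Off-target editing was first compared by the number of listed A-to-G positions with a coverage of at least 10 reads, which asks how widely each fusion edits. Transfected libraries listed many more than untransfected cells, and no pair of fusions differed by more than the spread between libraries. The mean number per library was 96440 ± 40000 (SD, n = 4) for dCas9, 94550 ± 23800 (SD, n = 4) for dCas13b and 87680 ± 15800 (SD, n = 4) for dCas13d, against 9400 ± 2630 (SD, n = 3) in untransfected cells. Most positions rested on little: from 56.8% to 73.2% of the positions in a transfected list, and from 83.1% to 86.4% in an untransfected one, had a single edited read. Positions with a deposited confidence of at least 0.99 numbered 10060 ± 1210 (SD, n = 4) for dCas9, 11680 ± 1910 (SD, n = 4) for dCas13b, 9647 ± 2180 (SD, n = 4) for dCas13d and 721.7 ± 336 (SD, n = 3) in untransfected cells.

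The ratio of geometric means between transfected and untransfected libraries was 9.75 (two-sided exact permutation test, p = 0.0022, the smallest of 455 arrangements; 0.011 adjusted over the 5 comparisons of site number). Median coverage of listed positions was 61 to 118 reads in transfected and 11 to 12 reads in untransfected libraries. The highest coverage was 1069 to 1096 reads in each transfected list and 78 to 90 reads in each untransfected one. Read totals alone do not account for this gap, since the untransfected totals lay within the range of the transfected ones. The dCas9 NT libraries, the shallowest transfected ones, had medians of 61 and 98 reads. The ratio of 9.75 can therefore not be read as editing alone. The ratio depended on the sites counted: it was 19.8 with a coverage of at least 20, 6.35 with at least 5, 15.2 with a confidence of at least 0.99 and 5.95 with a fraction of at least 0.1 (permutation p = 0.0022 for each). After thinning to one coverage, a setting chosen after seeing the data, the ratio was 2.05 (permutation p = 0.0022). Thinning kept a fixed share of the reads of each library, from 0.127 to 0.25 in transfected and from 0.718 to 1 in untransfected ones. Positions near the highest coverage therefore stayed deeper in transfected lists, and this ratio cannot be read as editing alone either. Divided by the total coverage of listed positions the ratio turned to 0.115 (permutation p = 0.0022). In that measure the untransfected lists with their low coverage stand higher. The dCas13b to dCas9 ratio was 1.03 (exact permutation p = 0.914), the dCas13d to dCas9 ratio 0.966 (exact permutation p = 0.914) and the dCas13b to dCas13d ratio 1.07 (exact permutation p = 0.657), where 70 arrangements allow no p below 0.0286. Per total coverage, the dCas13b to dCas13d ratio was 0.84 (exact permutation p = 0.0286). Since this divides by the coverage of the listed positions themselves, it mostly reflects their mean coverage and not how widely a fusion edits.

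CYFIP2 guide libraries listed 107000 ± 26200 positions (SD, n = 6) and NT guide libraries 78790 ± 17800 (SD, n = 6). The ratio of geometric means within fusions was 1.35 and did not pass the exact permutation test (p = 0.102). Without dCas13b CYFIP2 replicate 2 it was 1.49 (exact permutation p = 0.0278). It was 0.923 among positions with a confidence of at least 0.99 (exact permutation p = 0.528) and 1.13 after thinning to one coverage (exact permutation p = 0.343). Within a single fusion 2 libraries face 2, and no p below 0.05 can be reached.

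**Figure D2:**
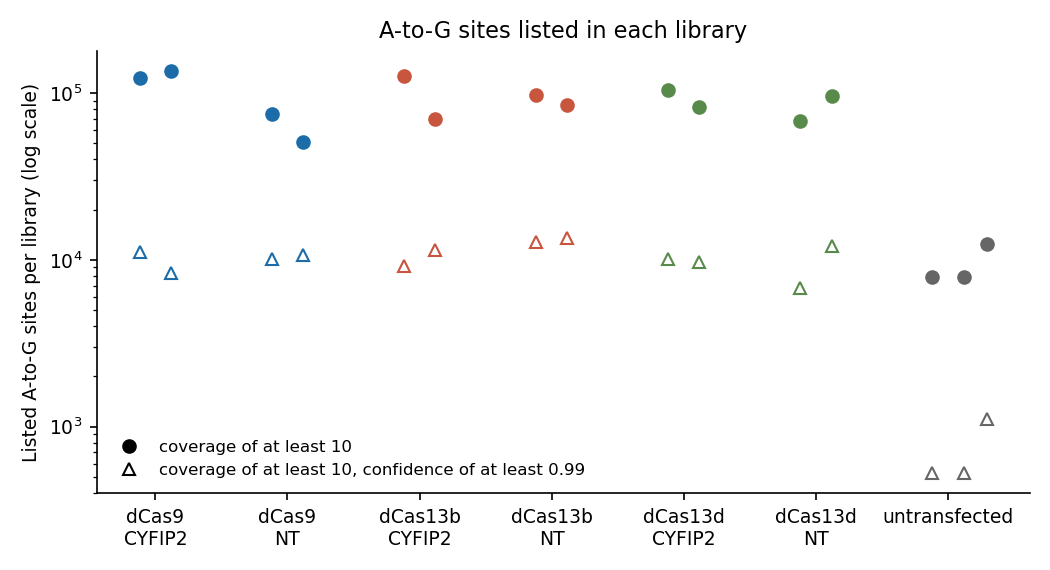
Number of listed A-to-G sites per library on a log scale, by fusion and guide; filled circles have a coverage of at least 10 reads, open triangles also a confidence of at least 0.99. Transfected libraries hold 50985 to 135904 sites with a coverage of at least 10 and untransfected libraries 7856 to 12441.

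The sharing of positions was compared between libraries of the same group and of other groups. The share of the shorter list found in the other was 16.2% ± 2.92 (SD, n = 6 pairs) for libraries of the same group, 16.9% ± 2.88 (SD, n = 12 pairs) for the same fusion with the other guide and 15.4% ± 2.32 (SD, n = 24 pairs) for the same guide in another fusion. Regrouping the 12 libraries at random gave p = 0.271 for the excess within groups (permutation test with 100000 draws). Among positions with a confidence of at least 0.99 the share within groups was 21.3% ± 6.99 (SD, n = 6 pairs), against 20% ± 5.35 (SD, n = 12 pairs) for the same fusion with the other guide and 19.6% ± 5.0 (SD, n = 24 pairs) for the same guide in another fusion. Listed positions often stood close together. In transfected libraries 52.05% had another within 50 nt on the same strand, against 21.5% in untransfected libraries, a difference of 30.6 percentage points (exact permutation p = 0.0022), which was 18.2 within 20 nt and 37.5 within 100 nt (exact permutation p = 0.0022 for both). A longer list holds more neighbours by its length alone. With each list drawn at random down to 7856 positions, a setting chosen after seeing the data, the shares were 9.46% and 20.2%, a difference of -10.8 percentage points (exact permutation p = 0.0022). A random draw also breaks up groups of neighbours, so which lists are more clustered stays open. The widest difference between fusions was -1.09 percentage points for dCas13d against dCas9 (exact permutation p = 0.629). The CYFIP2 guide minus NT guide difference was 2.48 percentage points (exact permutation p = 0.25), 4.12 without dCas13b CYFIP2 replicate 2 (exact permutation p = 0.0278) and 0.833 without replicate 1 of that group (exact permutation p = 0.741).

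Positions listed in every transfected library and in no untransfected one, with a coverage of at least 20 throughout and a level under 95%, were ranked by their mean level. The untransfected lists have a median coverage of 11 to 12 reads and an unlisted position no stated depth, so native editing or a sequence variant at these positions was not tested. The first 10 had mean levels from 24.7% to 80.7%. The highest was position 98942688 on the plus strand of chromosome 12, at 80.7% ± 8.4 (SD, n = 12) with a coverage of 27 to 91 reads. It was followed by position 156258205 on the minus strand of chromosome 3, at 64.4% ± 9.0 (SD, n = 12), and position 43495570 on the minus strand of chromosome 5, at 51.2% ± 11.2 (SD, n = 12). Genes and regions around these positions are not given, because no hg19 annotation was used here.

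The level of editing at shared positions asks whether the fusions edit the same off-targets to the same degree. Of 1141 positions covered by at least 10 reads in all 12 transfected libraries, 45 differed between fusions at an adjusted p under 0.05, and the highest level lay with dCas9 at 27 of them, with dCas13b at 18 and with dCas13d at 0. Position 53262149 on the minus strand of chromosome 3 was edited at 8.48% ± 4.37 by dCas9, 1.23% ± 1.01 by dCas13b and 0.305% ± 0.138 by dCas13d (SD, n = 4 each; adjusted p = 1.45e-06). Position 98510125 on the plus strand of chromosome 10 stood at 22.9% ± 7.11, 4.88% ± 4.37 and 11.6% ± 4.38 in the same order (adjusted p = 0.000559). Position 89174300 on the plus strand of chromosome 15 stood at 16.0% ± 4.71, 3.50% ± 2.03 and 4.28% ± 1.72 (adjusted p = 0.000559). In the other direction, position 23689656 on the plus strand of chromosome X stood at 1.09% ± 0.539 for dCas9, 4.37% ± 0.903 for dCas13b and 1.41% ± 0.766 for dCas13d (adjusted p = 0.000559). Position 17972205 on the plus strand of chromosome 19 stood at 0.776% ± 0.239, 4.47% ± 1.57 and 2.77% ± 0.98 (adjusted p = 0.000652). Read depth at these 5 positions ranged from 63 to 993. At position 53262149, with 318 to 825 reads, the dCas13d level rests on few edited reads. Positions had to be listed in every transfected library, so such a level is near the lowest that could enter.

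These adjusted p-values come from a quasi-binomial fit of edited and unedited reads with its dispersion moderated by limma. With limma on the arcsine square root of the fraction, 0 positions passed. The 5 positions with the smallest quasi-binomial p-values among those highest in dCas9, and the 5 among those lowest in dCas9, were also looked up. Their adjusted p-values in that limma fit were from 0.172 to 0.329. Leaving out one library gave 22 positions without dCas9 CYFIP2 replicate 1, 116 without dCas9 NT replicate 1, 24 and 26 without dCas13d NT replicates 2 and 1, 28 without dCas13d CYFIP2 replicate 2, and from 31 to 52 for the others. Restricting the test to positions with a confidence of at least 0.99 gave 8 of 384. By pairs of fusions, over the positions that each pair shares, dCas13d was lower than dCas9 at 39 positions and higher at 1, dCas13b was lower than dCas9 at 10 and higher at 8, and dCas13b was higher than dCas13d at 5 and lower at 1.

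Between guides, 0 of the 1141 positions passed the same test (99 had an unadjusted p under 0.05; limma on the arcsine scale also passed 0), though 15 passed without dCas9 NT replicate 1, and no position showed a guide effect that differed between fusions. The smallest p belonged to position 176118188 on the minus strand of chromosome 1, edited at 47.6% ± 5.86 with the CYFIP2 guide and 28.1% ± 7.11 with the NT guide (SD, n = 6; limma-moderated adjusted p = 0.285) and also listed in 2 untransfected libraries. Among lower levels with the CYFIP2 guide it belonged to position 83205593 on the minus strand of chromosome 15, at 16.9% ± 6.04 and 23.2% ± 11.4 (SD, n = 6; limma-moderated adjusted p = 0.285). Neither passed. On simulated data, with a preset spread not estimated from these libraries, a log odds change of 1 was found at 41% of changed positions. Smaller guide effects could therefore be missed. The estimates leaned one way: 762 lay below 0, with less editing under the CYFIP2 guide, and 379 above. Over 729 positions listed in all transfected libraries and in no untransfected one, the mean level was 4.18% ± 0.37 (SD, n = 6) with the CYFIP2 guide and 5.10% ± 1.07 (SD, n = 6) with the NT guide. This measure was chosen after seeing the data, and its difference of -0.92 percentage points had an exact permutation p of 0.00926, the smallest possible (0.037 adjusted over 4 tests of this level). Without dCas9 NT replicate 2 it was -0.585 percentage points (exact permutation p = 0.00926). It was -0.736 over 660 shared positions with a coverage of at least 50 and -2.51 over 60 with a pooled level of at least 0.1 (exact permutation p = 0.00926 for both, not adjusted). Over the 16 positions that met both conditions it was -1.99 (exact permutation p = 0.25).

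ADARB1 expression in these libraries can hold reads from the deaminase domain of the plasmid, and it separated the fusions completely. It was 63.5 ± 36.1 TPM (SD, n = 4) for dCas9, 223 ± 40.0 TPM (SD, n = 4) for dCas13b and 436 ± 111 TPM (SD, n = 4) for dCas13d, against 9.45 ± 0.732 TPM (SD, n = 3) in untransfected cells. The differences in mean log2(TPM + 1) were 2.03 for dCas13b over dCas9 and 2.98 for dCas13d over dCas9, each with an exact permutation p of 0.0286, the smallest possible for 4 against 4. In limma over all genes neither passed (adjusted p = 1 and 0.105). Adjusted over the list alone, among the deaminase genes, both did (limma adjusted p = 0.0171 and 0.000914). With the gene length trend removed, a setting chosen after seeing the data, dCas13d over dCas9 passed over all genes (limma adjusted p = 0.0139). In that setting dCas13b over dCas9 did not (limma adjusted p = 0.249). dCas9 NT replicate 2 had the lowest ADARB1 level of the transfected libraries, at 17.3 TPM, and replicate 1 of that group 105.6 TPM. ADAR, the other editing enzyme, stood at 25.1 to 137.7 TPM in transfected libraries, and ADARB2 was listed at 0 in all libraries.

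Whether more fusion RNA goes with more edited positions was tested across the 12 transfected libraries after centring each fusion on its mean, because the ADARB1 levels of the 3 fusions do not overlap and a pooled correlation would compare fusions. Pearson's r between log2(ADARB1 TPM + 1) and the log10 number of positions was 0.532 (permutation within fusions, p = 0.289) and Spearman's rho 0.427 (permutation p = 0.258). Without the 2 libraries farthest from the median ADARB1 level r was 0.257 (permutation p = 0.524), and without dCas9 NT replicate 2 alone it was -0.198 (permutation p = 0.614). With the number of positions divided by their total coverage r was 0.781 (permutation p = 0.0142) and rho 0.713 (permutation p = 0.0114). That quotient is close to the inverse of the mean coverage of a listed position. It does not count edited positions at equal depth, so it does not answer whether more fusion RNA goes with more of them. After thinning, a setting chosen after seeing the data, r was 0.739 (permutation p = 0.0673) and rho 0.622 (permutation p = 0.0517). Neither passed. With a confidence of at least 0.99 as well, r was -0.164 (permutation p = 0.899). Across fusions the mean level at the 729 shared positions was higher for dCas13b than for dCas13d by 0.922 percentage points (exact permutation p = 0.0286, 0.0572 adjusted over 4 tests), and for dCas13d minus dCas9 the difference was -1.12 percentage points (exact permutation p = 0.0857, 0.114 adjusted over 4 tests). It was -1.09 with a coverage of at least 50 and -1.13 after thinning to one coverage (exact permutation p = 0.0286 for both, not adjusted), and -1.29 over the 60 shared positions with a pooled level of at least 0.1 (exact permutation p = 0.4). Over the 16 positions that also had a coverage of at least 50 it was -3.92 (exact permutation p = 0.0286, not adjusted). The difference at the 729 positions leans on dCas9 NT replicate 2, at 7.02%. The other dCas9 libraries stood at 4.12%, 4.17% and 5.01%, and the dCas13d libraries, from 3.74% to 4.25%, overlapped them.

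**Figure D3:**
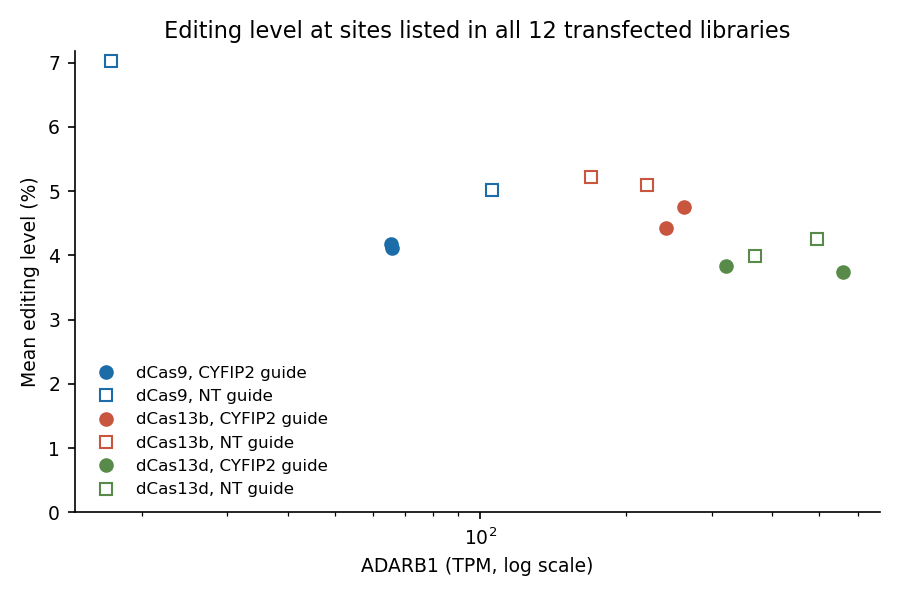
Mean editing level (%) at the 729 positions listed in all transfected libraries and in no untransfected one, against ADARB1 expression in TPM on a log scale; each point is 1 library, filled for the CYFIP2 guide and open for the NT guide. The dCas13d libraries hold the highest ADARB1 levels, from 320.7 to 560.2 TPM, and dCas9 NT replicate 2 the lowest, at 17.3 TPM.

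Expression was compared between fusions over both guides to ask how the choice of Cas protein changes the transcriptome. The integrated stress response is switched on by eIF2 alpha kinases under amino acid shortage or misfolded protein. Of the 29 tested genes of its list, 13 rose in dCas13d against dCas9 and 14 were lower in dCas13b than in dCas13d, adjusted over the list alone (limma); 0 passed over all genes. The camera test with its preset correlation called the list in both contrasts (limma adjusted p = 7.71e-06 against dCas9 and 3.13e-08 between dCas13b and dCas13d), but with an estimated correlation the adjusted p was 0.992 for both. TRIB3, a pseudokinase induced by ATF4, stood at 65.8 ± 4.18 TPM (SD, n = 4) with dCas13d, 46.4 ± 2.71 TPM (SD, n = 4) with dCas9 and 42.0 ± 9.02 TPM (SD, n = 4) with dCas13b. In the same order CEBPB, a bZIP transcription factor, stood at 36.6 ± 5.66, 23.2 ± 3.47 and 24.4 ± 6.86 TPM (SD, n = 4 each). SHMT2, an enzyme of serine and glycine metabolism, stood at 304 ± 27.8, 218 ± 55.3 and 224 ± 43.5 TPM (SD, n = 4 each). WARS1, which charges tRNA with tryptophan, stood at 73.5 ± 8.50, 49.7 ± 10.2 and 51.9 ± 11.5 TPM (SD, n = 4 each). The members passing in both contrasts included these and ATF3, PCK2, ATF5, CARS1, PHGDH, SLC7A5, SLC3A2 and AARS1. With the gene length trend removed, the log2 differences of all 13 for dCas13d over dCas9 became smaller but stayed above 0. SLC3A2 went from 0.26 to 0.01, PHGDH from 0.31 to 0.05 and CARS1 from 0.43 to 0.10. TRIB3 went from 0.49 to 0.35 and CEBPB from 0.63 to 0.57.

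The mean log2 level of the 29 members was higher in each dCas13d library (0.185 to 0.377 relative to the mean of all 12) than in any dCas9 library (-0.613 to 0.115) or dCas13b library (-0.399 to 0.074). The lowest values belong to libraries that stand apart on the first component: dCas9 NT replicate 2 at -0.613 and the dCas13b NT libraries at -0.399 and -0.345. The other dCas9 and dCas13b libraries lay from -0.036 to 0.115. The exact permutation p was 0.0286 for both fusions, the smallest possible, and 0.107 when adjusted over the 15 such tests; this summary was chosen after seeing the data. The median of all tested genes also moved, by 0.19 on the log2 scale for dCas13d over dCas9 and by -0.19 for dCas13b over dCas13d. With the deposited TPM the list means of dCas13d lay 0.40 above dCas9 and 0.44 above dCas13b. After removing each library's trend with gene length these differences were 0.21 and 0.25 (exact permutation p = 0.0286 for both). Of 25 tested genes of the endoplasmic reticulum unfolded protein response, 1 rose in dCas13d against dCas9 and 2 were lower in dCas13b than in dCas13d, adjusted over the list alone (limma), and 0 passed over all genes. The camera adjusted p was 0.0154 and 0.00262 (limma), and 0.992 with an estimated correlation for both. HSPA5, the chaperone BiP, stood at 491 ± 39.3 TPM (SD, n = 4) with dCas13d, 357 ± 44.9 TPM with dCas9 and 346 ± 65.6 TPM with dCas13b (limma, adjusted p = 0.00758 and 0.00312, adjusted over the list alone). MANF was lower in dCas13b than in dCas13d by a log2 difference of -0.44 (limma, adjusted p = 0.0222, adjusted over the list alone). After removing the length trend the mean of this list did not pass against dCas9 (0.07, exact permutation p = 0.114), while against dCas13b the difference was 0.1 (exact permutation p = 0.0286).

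**Figure D4:**
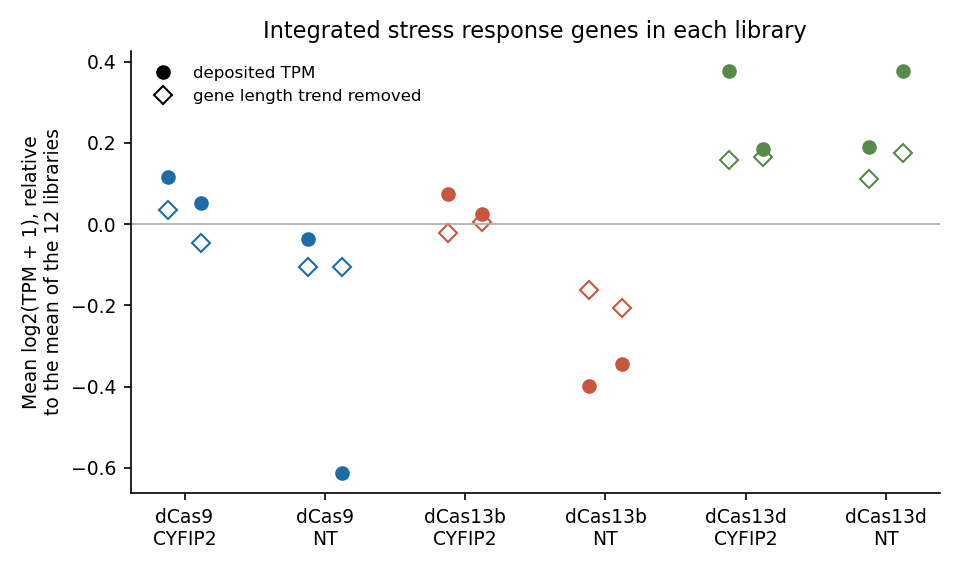
Mean log2(TPM + 1) of the 29 tested integrated stress response genes in each library, relative to the mean of the 12 transfected libraries; filled circles use the deposited TPM and open diamonds the values after removing each library's trend with gene length. The 4 dCas13d libraries lie from 0.185 to 0.377 with the deposited TPM, above every library of the other fusions.

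Over all 15679 tested genes, 3 passed between dCas13d and dCas9 (2 higher, 1 lower in dCas13d), 3 between dCas13b and dCas13d (1 higher, 2 lower in dCas13b) and 0 between dCas13b and dCas9 (limma; 2386, 2152 and 281 at an unadjusted p under 0.05). With voom, limma's method for read counts, on the recovered reads the counts were 3, 1 and 0. NPM1P27, a pseudogene, stood at 155.5 to 211.5 TPM in the 4 dCas13d libraries and at 34.65 to 57.76 TPM in the other 8, with log2 differences of 1.88 over dCas9 (limma adjusted p = 0.00645) and -1.95 for dCas13b minus dCas13d (limma adjusted p = 0.00657). RPL12P4, also a pseudogene, stood at 8.903 to 21.74 TPM with dCas13d and at 30.46 to 40.13 TPM elsewhere, with log2 differences of -1.42 against dCas9 (limma adjusted p = 0.00645) and 1.22 for dCas13b over dCas13d (limma adjusted p = 0.0256). Reads of pseudogenes can be shared with their parent genes, so both are uncertain. NDUFAF8, an assembly factor of respiratory complex I, stood at 63.36 to 111.5 TPM with dCas13d and 27.48 to 36.38 TPM with dCas13b (log2 difference -1.42, limma adjusted p = 0.0303). SNORD59A, a small nucleolar RNA of 75 nt that a poly(A) library holds poorly, had a log2 difference of 2.95 for dCas13d over dCas9 (limma adjusted p = 0.0141). Between dCas13b and dCas9 the smallest p belonged to RNU2-32P (log2 difference 1.62, limma adjusted p = 0.397), which did not pass. Of the heat shock list, HSPA6 had a log2 difference of -0.79 (limma, adjusted p = 0.0447, adjusted over the list alone).

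Other gene lists were compared between fusions relative to the shift of all genes. Camera called immediate early genes higher with dCas13d than with dCas9 (limma camera adjusted p = 0.000734, median log2 difference 0.48 over 23 genes) and lower in dCas13b than in dCas13d (limma camera adjusted p = 0.00648, median -0.40). With an estimated correlation the adjusted p was 0.992 for both, and 0 members passed adjusted over the list alone. Camera called cytosolic ribosomal protein genes (58 tested) and nuclear oxidative phosphorylation genes (34 tested) lower with dCas13d than with dCas9, with median log2 differences of -0.23 and -0.24 (limma camera adjusted p = 1.22e-18 and 8.63e-09). It called them higher in dCas13b than in dCas13d, with medians of 0.26 and 0.20 (limma camera adjusted p = 4.03e-23 and 2.45e-10). With an estimated correlation the adjusted p was 0.992 for ribosomal protein genes and 0.932 for oxidative phosphorylation, and 0 members of either list passed adjusted over the list alone. The list means of the libraries overlapped and did not pass. For dCas13d minus dCas9 they differed by -0.23 for ribosomal protein genes (exact permutation p = 0.257) and by -0.18 for oxidative phosphorylation (exact permutation p = 0.0857). For dCas13d minus dCas13b they differed by -0.24 and -0.18 (exact permutation p = 0.171 for both). The RNA deaminase list was called for dCas13b over dCas9 (camera adjusted p = 0.0363; adjusted p = 0.992 with an estimated correlation), and of its 17 tested members ADARB1 alone passed adjusted over the list alone. The dCas9 and dCas13b NT libraries that stand apart on the first component take part in each of these contrasts. Without dCas9 NT replicate 1, which leaves replicate 2 as the only library of its group, 6639 genes passed between dCas13d and dCas9 and 2939 between dCas13b and dCas13d (limma). Without replicate 2 the counts were 6 and 2956.

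The guide comparison asks whether targeting CYFIP2 changes expression beyond what a non-targeting guide does. CYFIP2 itself did not change measurably: it stood at 28.6 ± 0.634 TPM with the CYFIP2 guide and 22.3 ± 18.4 TPM with the NT guide for dCas9 (SD, n = 2 each). In the same order it stood at 32.3 ± 3.03 and 19.4 ± 3.72 TPM for dCas13b and at 35.7 ± 11.8 and 39.4 ± 6 TPM for dCas13d (SD, n = 2 each). It was 29.3 ± 0.841 TPM (SD, n = 3) in untransfected cells. Its log2 difference between guides over the 3 fusions was 0.39 (SE 0.27, limma adjusted p = 0.404). NCKAP1, its partner in the WAVE complex, had a log2 difference of 0.38 (SE 0.21, limma adjusted p = 0.355). The median of all tested genes moved by 0.20 over the 3 fusions, 0.34 for dCas9, 0.21 for dCas13b and 0.02 for dCas13d on the log2 scale, so small shifts of single genes are to be read against it.

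Over the 3 fusions, 3 genes passed in limma (2 higher and 1 lower with the CYFIP2 guide; 2068 at an unadjusted p under 0.05). SNORA3B, a small nucleolar RNA, had a log2 difference of -1 (limma adjusted p = 0.0485). The others were ENSG00000250917, at 1.30 (limma adjusted p = 0.0485), and ENSG00000221051, of 88 nt, at 1.93 (adjusted p = 0.0382), whose functions the tables do not give. For dCas9 alone 1 gene passed (limma; 1715 at an unadjusted p under 0.05): ENSG00000250917 with a log2 difference of 2.86 (adjusted p = 0.0175), listed at 0 in both NT libraries. For dCas13b alone 0 passed (limma; 2150 at an unadjusted p under 0.05), with the smallest p at ENSG00000221051 (log2 difference 3.14, adjusted p = 0.0617) and SNORD59A (log2 difference 3.69, adjusted p = 0.0617). For dCas13d alone 2 passed (limma; 563 at an unadjusted p under 0.05): MIR548AR at 2.94 and ENSG00000263660 at -3.08 (adjusted p = 0.0246 for both), each listed at 0 in both libraries of one group. All of these but ENSG00000250917 are shorter than 150 nt, and with genes of at least 5 TPM alone 0 passed in any guide comparison. With voom 0 passed in each of the 4 guide comparisons. The guide effect differed between fusions at 0 genes (limma; 1055 at an unadjusted p under 0.05).

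Single libraries moved these counts. Without dCas9 NT replicate 1, 6828 genes passed over the 3 fusions, 7534 for dCas9, 2554 for dCas13b and 2 for dCas13d, and the guide effect differed between fusions at 3423 (limma). Without dCas9 NT replicate 2 the counts were 3, 4, 2581 and 2, and 807 for the difference between fusions. On simulated data with the spread of these libraries, limma found 30% of genes with a log2 change of 1 for dCas9 and 75% over the 3 fusions, with 5 and 4 false calls among 15679 genes. With the spread of the groups other than dCas9 NT it found 55% and 90%. The simulation drew each gene independently with the same spread in every library, without the first component or the wider dCas9 NT spread. Its recovery and false calls may therefore not hold here. Regrouping the real libraries gave up to 4856 calls in a simpler fit.

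Among gene lists, 7 of 29 tested hypoxia and glycolysis genes rose with the CYFIP2 guide for dCas9, adjusted over the list alone, and 0 over all genes (limma). The list's camera adjusted p was 4.85e-07 (limma), 0.000168 without NT replicate 2 and 0.992 with an estimated correlation. P4HA1, a collagen prolyl hydroxylase, rose by 0.89 on the log2 scale (limma adjusted p = 0.0122 over the list) and DDIT4, an inhibitor of mTORC1 signalling, by 0.63 (limma adjusted p = 0.0122). SLC2A3, a glucose transporter, rose by 1.03 (limma adjusted p = 0.028) and PGK1, a glycolytic kinase, by 0.48 (limma adjusted p = 0.0286). The list mean, relative to all 12 libraries, was 0.203 and 0.204 with the CYFIP2 guide, -0.036 in NT replicate 1 and -0.673 in NT replicate 2, the library that stands apart on the first component. After removing the gene length trend PGK1 stood at 0.08 and LDHA at 0.01, while camera still called the list (limma camera adjusted p = 0.000155), with means of 0.119 and 0.086 with the CYFIP2 guide and -0.121 and -0.074 with the NT guide. In the interferon list IFI6 was lower for dCas9 with the CYFIP2 guide (log2 difference -0.98, limma, adjusted p = 0.00559, adjusted over the list alone), at 30.3 and 27.93 TPM against 53.83 and 63.52 TPM. In the other fusions its mean was higher with the CYFIP2 guide. It stood at 46.9 ± 2.58 against 31.2 ± 3.18 TPM for dCas13b and at 38.6 ± 5.52 against 33.4 ± 2.25 TPM for dCas13d (SD, n = 2 each), where the libraries overlapped. IFI35 was higher for dCas9 with the CYFIP2 guide (log2 difference 1.58, limma, adjusted p = 0.0225, adjusted over the list alone), at a low level of 2.8 ± 2.16 TPM over the dCas9 libraries (SD, n = 4). For dCas13b, HSPA1B of the heat shock list was higher by 0.84 (limma, adjusted p = 0.00911, adjusted over the list alone). Over the 3 fusions HSPA5 rose by 0.30 and HSP90B1 by 0.26 (limma, adjusted p = 0.0417 and 0.0463, adjusted over the list alone).

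Over all lists and comparisons, 33 of 154 camera tests passed with the preset correlation, 0 with an estimated correlation (adjusted p = 0.932 or 0.992 for the 33) and 0 by fry, which asks whether a list's genes move one way on balance. Over the 3 fusions the integrated stress response list was higher with the CYFIP2 guide (limma camera adjusted p = 0.00648), and ribosomal protein, oxidative phosphorylation, histone and p53 target lists were lower relative to all genes (limma camera adjusted p = 1.63e-27, 7.68e-16, 0.000311 and 0.0271). With an estimated correlation, adjusted p = 0.992 held for the integrated stress response, ribosomal protein and p53 lists and 0.932 for the other 2. The p53 list had a median of 0.08 and a mean of 0.05, so its call is a lag behind the shift of all genes and not a fall. For dCas9 without NT replicate 2, the ribosomal protein, oxidative phosphorylation, interferon, histone and integrated stress response lists no longer passed (adjusted p = 0.756, 0.374, 0.438, 0.104 and 0.127, limma camera). Mitochondrially encoded genes were called lower for dCas9, where their median of 0.06 lay below that of all genes, and higher for dCas13b and dCas13d (limma camera adjusted p = 0.00643, 0.0452 and 0.000734; adjusted p = 0.992 with an estimated correlation). Developmental regulators and p53 targets were lower for dCas13d (limma camera adjusted p = 0.0233 and 0.00464), and immediate early genes higher for dCas13b (limma camera adjusted p = 0.002); for all 3, adjusted p = 0.992 with an estimated correlation. The remaining 10 tested lists, of WAVE complex, cytokine, heat shock, cholesterol, G1/S, G2/M, nonsense-mediated decay, splicing, fibroblast and known ADAR target genes, passed in no comparison with the reported setting. Under other settings 4 of them passed in limma camera. Cytokine genes were lower in dCas13b than in dCas13d (adjusted p = 0.0439 with pseudocount 0.1 and 0.00631 with the length trend removed). Heat shock genes were lower for the dCas9 guide with that trend removed (adjusted p = 0.00961). Known ADAR target genes were higher over the 3 fusions with it removed (adjusted p = 0.0409), and for the dCas13b guide without dCas9 NT replicate 2 (adjusted p = 0.0301). Splicing genes were lower in dCas13b than in dCas9 without that library (adjusted p = 0.046).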

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

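Removal of the gene length trend, genes of at least 300 nt, voom, library weights, thinning to one coverage, equal list lengths, and a coverage of at least 50 were chosen after seeing the data. The other settings were planned. Over planned and added settings, 231 values of the results that answer a comparison were computed, of which 138 kept their direction and side of the threshold or their count within 1.5 times, 1 became stronger, 74 moved and 18 reversed. With one library left out, 190 of 267 kept, 2 became stronger, 59 moved and 16 reversed. For single named genes and positions, 589 of 735 values under other settings kept, 64 became weaker, 78 stronger and 4 reversed. With one library left out, 654 of 805 kept, 94 became weaker, 55 stronger and 2 reversed. Unless a reason is given, the cause was not tested.

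Counts of genes that passed in limma are given in the order guide over the 3 fusions, guide for dCas9, dCas13b and dCas13d, then dCas13b against dCas9, dCas13d against dCas9, dCas13b against dCas13d, and genes whose guide effect differs between fusions; counts that did not move are left out with the name of their comparison. The reported counts are 3, 1, 0, 2, 0, 3, 3 and 0. With pseudocount 0.1 the 4 guide counts were 5, 8, 2 and 0 and that of dCas13d against dCas9 was 6. With no filter on low values they were 9, 21, 11 and 25, then 10 for dCas13d against dCas9, 9 for dCas13b against dCas13d and 8 for the difference between fusions. With a mean of at least 5 TPM they were 0 for the guide over the 3 fusions, 0 for dCas9 and 0 for dCas13d, where fewer genes were tested. Median centred values gave 1, 0, 1 and 0 for the guide and 1 for dCas13b against dCas13d. Quantile normalized values gave 1, 2, 1 and 0 for the guide. With the replicate block they were 0 over the 3 fusions, 0 for dCas9 and 0 for dCas13d.

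With only the groups in the contrast fitted, the guide counts were 0 for dCas9, 954 for dCas13b and 0 for dCas13d, that of dCas13d against dCas9 was 0 and that of dCas13b against dCas13d 1689. With no mean-variance trend the counts were 2 for the dCas9 guide, 6 for the dCas13b guide, 5 for dCas13d against dCas9 and 3 for the difference between fusions. With the gene length trend removed they were 1, 2, 1 and 0 for the guide and 5 for dCas13d against dCas9. With that trend removed and without dCas9 NT replicate 1 all 8 counts were 3501, 3198, 2688, 0, 30, 5655, 2021 and 2361. With it removed and without dCas9 NT replicate 2 they were 3, 3, 2716, 0, 3, 6, 2069 and 1736. Among genes of at least 300 nt the counts were 0 for the guide over the 3 fusions and 0 for dCas13d, where the short genes named in the report were not tested. With voom they were 0 over the 3 fusions, 0 for dCas9, 0 for dCas13d and 1 for dCas13b against dCas13d. With library weights they were 0 over the 3 fusions, 0 for dCas9, 3005 for dCas13b, 0 for dCas13d and 2245 for dCas13b against dCas13d; the weights gave the dCas9 NT libraries the least influence, at 0.152.

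Both dCas9 NT libraries enter the spread that all contrasts share. In a setting that leaves out a library, its partner is assumed to vary like the other groups. The lowest and highest counts with one library left out were 0 and 6828 for the guide over the 3 fusions, 0 and 7534 for dCas9, 0 and 2581 for dCas13b, and 0 and 3 for dCas13d. They were 0 and 16 for dCas13b against dCas9, 0 and 6639 for dCas13d against dCas9, 0 and 2956 for dCas13b against dCas13d, and 0 and 3423 for the difference between fusions. The highest came without dCas9 NT replicate 1, except for the dCas13b guide and dCas13b against dCas13d, where they came without replicate 2, and for the dCas13d guide.

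Gene list calls numbered 33, 0 with an estimated correlation, 0 by fry and from 29 to 39 with one library left out. Positions whose level differs between fusions numbered 45, 8 with a confidence of at least 0.99, 4 with a fraction of at least 0.1, where fewer positions were tested, 0 with limma on the arcsine square root, and from 22 to 116 with one library left out. Positions that differ by guide numbered 0, and from 0 to 15. Planned use of positions listed in both libraries of the groups compared was run by pairs of fusions and gave 52.

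The ratio of site numbers between transfected and untransfected libraries was 9.75, and 19.8 with a coverage of at least 20, 6.35 with at least 5, 15.2 with a confidence of at least 0.99 and 5.95 with a fraction of at least 0.1. It was 2.05 after thinning, 1.91 after thinning with that confidence (exact permutation p = 0.0396), 0.115 per total listed coverage, and from 9.02 to 11.4 with one library left out. For dCas13b to dCas9 it was 1.03, and 0.923 per total coverage, 0.925 with a coverage of at least 20 in both libraries, 0.898 after thinning, 0.983 after thinning with a confidence of at least 0.99 and 0.95 after thinning with a fraction of at least 0.1, with a range from 0.854 to 1.18. For dCas13d to dCas9 it was 0.966, and 1 with a fraction of at least 0.1 and 1.1 per total coverage, with a range from 0.8 to 1.11. For dCas13b to dCas13d it was 1.07, and 0.84 per total coverage, with a range from 0.963 to 1.17. For the guide it was 1.35, and 0.923 with a confidence of at least 0.99, 0.721 after thinning with that confidence and 0.871 after thinning with a fraction of at least 0.1, with a range from 1.23 to 1.49. None of these fusion and guide ratios passed under these settings, except per total coverage for dCas13b to dCas13d (exact permutation p = 0.0286) and the guide without dCas13b CYFIP2 replicate 2 (exact permutation p = 0.0278).

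Editing at the targeted position differed by 8.55 to 12.4 percentage points between guides with one library left out. The correlation of ADARB1 with the number of positions was 0.532, -0.026 with a confidence of at least 0.99 and 0.781 per total coverage. It was 0.739 after thinning, -0.164 after thinning with that confidence, and from -0.198 to 0.791 with one library left out. Sharing within groups was 16.2%, 21.3% with a confidence of at least 0.99, 19.2% with a fraction of at least 0.1, and from 15.4% to 16.9% with one library left out. The share of positions with a neighbour differed between transfected and untransfected libraries by 30.6 percentage points within 50 nt, 18.2 within 20 nt and 37.5 within 100 nt. With equal list lengths it reversed to -10.78, and stood at 0.05 for dCas13d against dCas9, -0.63 for dCas13b against dCas13d and -1.84 for the guide. With one library left out it differed by 30.1 to 31.1, by -1.6 to 1.68 for dCas13b against dCas9, by -2.39 to 0.43 for dCas13d against dCas9, by -0.51 to 2.77 for dCas13b against dCas13d and by 0.83 to 4.12 for the guide. The targeted position had 25 to 64 reads in each library with the CYFIP2 guide.

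Single genes also reversed, each short of the threshold. The CYFIP2 guide difference was -0.11 over the 3 fusions and -0.31 for dCas9 with the length trend removed and without dCas9 NT replicate 2, -0.30 for dCas9 without that library alone, and from -0.5 to 0.16 for dCas13d with one library left out, the highest without dCas13d CYFIP2 replicate 2. With the length trend removed and without dCas9 NT replicate 1, HSP90B1 stood at -0.06 over the 3 fusions and PGK1 at -0.16 for dCas9.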

Other observations

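The tests of the gene length trend, of low depth, of thinning for the guide difference, of library quality and the amount of fusion RNA for both differences and of regrouped libraries for gene counts were chosen only after the result was seen; the remaining tests were set before their own result was known. No batch is given by the labels.

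Some stress genes stood apart between transfected and untransfected cells, which lie in separate paired-end and single-end tables and were not tested. GDF15, a secreted stress cytokine, had a median of 15.4 TPM over the transfected libraries (7.40 to 20.7) and 0.884 ± 0.462 TPM (SD, n = 3) in untransfected cells. CDKN1A, the p53-induced cell cycle inhibitor, stood at 184 TPM (101 to 193) and 40.4 ± 3.41 TPM (SD, n = 3), and HSPA6, an inducible heat shock protein, at 11.4 TPM (6.77 to 21.1) and 0.369 ± 0.088 TPM (SD, n = 3). The p53 target MDM2 stood at 45.4 TPM and 51.8 TPM. In the other direction HSPA5 stood at 403 TPM (286 to 543) and 1520 ± 158 TPM (SD, n = 3), ATF3 at 91.8 TPM (61.8 to 135) and 327 ± 30.8 TPM (SD, n = 3), and ADAR at 85.0 TPM (25.1 to 138) and 155 ± 6.55 TPM (SD, n = 3). TRIB3 stood at 48.6 TPM and 26.9 ± 1.42 TPM (SD, n = 3). Transfection and sequencing layout cannot be told apart in these values.

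The dCas9 NT libraries lay far apart in expression, with replicate 2 at 0.733 on the first component. Low sequencing depth as the whole cause is argued against by replicate 1, which had fewer reads, 11903762 against 13244498, and lay on the other side at -0.112. A trend with gene length was present, with a correlation across genes of -0.333 in replicate 2, but as the whole cause it is argued against. Over all tested genes the root mean square log2 difference between the 2 libraries was 1.033 before and 0.818 after removing the trend, 1.54 times the largest of the other groups (0.335 to 0.532), close to the bound of 1.5 set for this test. What lies behind the rest is open, and no biological explanation was tested.

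Editing at 729 shared positions was lower with the CYFIP2 guide than with the NT guide, by -0.92 percentage points (exact permutation p = 0.00926). It differed by -0.736 over 660 positions with a coverage of at least 50 and by -2.51 over 60 with a pooled level of at least 0.1 (exact permutation p = 0.00926 for both, not adjusted). Over the 16 positions that met both conditions it differed by -1.99, which did not pass (exact permutation p = 0.25). Selection of positions at lower coverage is argued against: after thinning to one coverage the difference was -0.89 (exact permutation p = 0.00926). Library quality was not measured, and the first component of expression, whose cause is open, stood in for it. It cannot be told apart, since the first component parts the guides completely in dCas13b. After removing the slope on that component within groups the difference was -0.381 (exact permutation p = 0.157). At positions listed in all untransfected libraries, where native editing also counts, the guide difference was -0.247 (exact permutation p = 0.454). More fusion RNA with the NT guide cannot be told apart either: ADARB1 was higher with the CYFIP2 guide by 0.32 on the log2 scale (exact permutation p = 0.556), within its spread. An effect of the guide itself stays open and was not tested apart from these.

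The same level was lowest in dCas13d: dCas13b lay above it by 0.92 percentage points (exact permutation p = 0.0286, the smallest possible, and 0.0572 adjusted over 4 tests). It was 2.81 with a pooled level of at least 0.1 (exact permutation p = 0.0571) and 1.03 with a coverage of at least 50 as well (exact permutation p = 0.657), neither of which passed. Less fusion RNA in dCas13d as the cause is argued against, since ADARB1 differed by -0.95 on the log2 scale for dCas13b minus dCas13d (exact permutation p = 0.0286). So is selection of positions, since the difference was 0.914 after thinning (exact permutation p = 0.0286). Library quality, for which the first component again stood in, cannot be told apart, since that component parts the 2 fusions completely under the NT guide. After removing the slope on it within groups the difference was 0.293 (exact permutation p = 0.2). A difference between the Cas proteins, or an effect of more fusion RNA, stays open as well and was not tested apart from the first component. RNA of the fusion may not reflect its protein, which was not measured.

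Regrouping the libraries asks whether chance can be excluded, using simpler fits than those reported above. For positions whose level differs between fusions, the real grouping gave 30 and the highest of the other groupings 7. Only 1 of 100 groupings, the real one, gave as many. The regrouping moved single libraries and so split the 2 libraries of a group. A likeness within groups, such as a shared culture, can therefore not be told apart from a difference between fusions. With limma on the arcsine square root 0 positions passed, so chance is not excluded. For genes between fusions chance cannot be excluded in 2 comparisons: for dCas13d against dCas9 the real count was 1, with 3 of 35 groupings as large and a highest of 2, and for dCas13b against dCas13d it was 1, with 6 of 35 and a highest of 6. Where the real count was 0, any grouping gives as many, so nothing is shown about chance. This holds for positions that differ by guide (100 of 100, highest 2), for genes by guide over the 3 fusions (100 of 100, highest 4856) and for genes between dCas13b and dCas9 (35 of 35, highest 5). The 4856 genes point to a structure of the samples other than the guide.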
